A study of Homo sapiens with 12 samples.

How the data were processed

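Total RNA from MCF7 xenograft tumours, taken after 28 days of treatment, was extracted with Trizol, made into biotinylated cRNA and hybridised to Affymetrix arrays. The 12 arrays formed 6 groups of 2, as the labels give them. The deposited log2 values had been made by the authors with RMA, which corrects background, normalises between arrays and summarises each probe set on the log2 scale. The version and settings of RMA are not stated. The values ran from 2.439 to 13.646. No genome build applies to probe sets, so no positions are given. No counts stand behind array values, and the number of arrays limits their precision.

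Of 22277 probe sets, 62 were controls, 19724 named 1 gene in the annotation, 568 named several and 1923 were not listed. Each of 12165 genes was represented by the probe set with the highest mean over all arrays among those naming that gene alone, a choice that applied to the 4505 genes with more than 1 probe set. AR had no such probe set. Probe sets naming no single gene were left out of the gene tests and are described in the closing section. Human probes can also read mouse transcripts of the host, which the values do not separate.

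Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit to the 12 arrays with 6 residual degrees of freedom and 10.4 in total. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes in each comparison and a threshold of 0.05. The 14 comparisons were the 5 treated groups against control, 6 between treated groups, 2 interactions and the average BMS-754807 effect. Median standard errors were 0.0955 for differences between groups, 0.135 for interactions and 0.0551 for the average. On simulated data with 12165 genes, 200 of them changed, the fit recovered 9.6% at 1.2-fold, 89% at 1.5-fold, 99.8% at 2-fold and 100% at 4-fold, and 5% of its calls were false.

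The comparisons, tests, named-gene rule, alternatives and 41 gene lists (965 genes, 849 measured) were fixed before the data were examined. Of the list symbols 4 were updated. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison, and again with an estimated correlation and with fry. A list shift of -0.3 was called in 10 of 10 simulations with either correlation (0.2 other lists on average), but correlated genes may differ. Counts of members adjusted over the list alone stand beside those over all genes.

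Named genes followed a rule. Against control they were the 6 largest rises and 6 largest falls among genes past the threshold whose arrays did not overlap between the groups. In other comparisons 4 of each were taken, and for interactions and the average the adjusted p alone applied. For each called list the 3 members with the smallest p in the direction of the call and 1 past the threshold in the other direction were added. ESR1, PGR, GREB1, TFF1, IGF1R, INSR, IRS1, IRS2, ERBB3, CCND1 and MKI67 were always eligible against control. Y-linked genes and XIST were not named. The text gives a part of the genes so chosen. HBB and HBA2 were named after their values were seen.

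Alternatives were the mean of a gene's probe sets, every probe set on its own, leaving out the dimmest 30% of genes, a trended robust prior, a fit to the compared groups alone, a further quantile normalisation, array weights, plate column as a block, replicate number as a block, a minimum of 1.5-fold and leaving out each array in turn. The plate column, 5 or 6, was read from the array positions in the labels, and that these are positions on a hybridisation plate is an inference. Control replicate 2, Tamoxifen replicate 2, Letrozole replicate 1 and Tamoxifen+BMS-754807 replicate 1 lay in column 5 and the other arrays in column 6. Overlap of changed genes was set beside 20 simulations of unchanged groups that share the control arrays. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.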

Results

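Gene expression was measured in tumours of MCF7, an established oestrogen receptor-positive human breast cancer line, grown as xenografts in mice treated for 28 days. The 12 arrays fell into 6 groups of 2. The groups were control, BMS-754807 (an inhibitor of the IGF-1 and insulin receptors), Tamoxifen (an oestrogen receptor modulator), Letrozole (an aromatase inhibitor) and both endocrine agents with BMS-754807. The labels give no doses. They call the arrays of a group biological replicates but name no separate animals, so a p value measures the spread between these samples alone. The number of arrays limits the precision of every value. Array medians lay between 4.10 and 4.16 on the log2 scale. Across genes, which are not independent replicates, arrays of a group correlated at 0.996 to 0.998. With the nearest array of another group the correlation was 0.994 to 0.997.

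**Figure D1:**
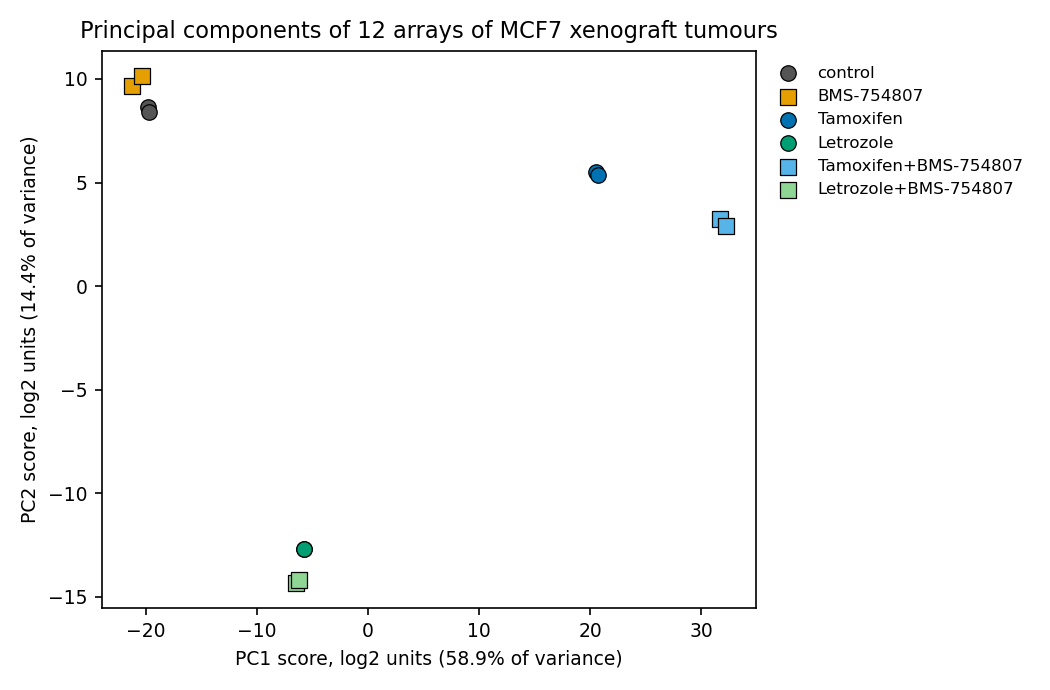
Scores of the 12 arrays on the first principal component (horizontal, 58.9% of the variance) and the second (vertical, 14.4%), in log2 units, with 1 point per array and 2 arrays per group. The tamoxifen groups lie to the right, the combination farthest at 31.71 and 32.26, and BMS-754807 lies near control.

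Differences are on the log2 scale, plus or minus the standard error from limma, with n = 2 arrays per group. In the genes given as largest rises or falls, the arrays of the groups did not overlap, a condition not set for interactions and the average. For each gene list the number of measured members past limma over all genes is followed by the median difference and by the adjusted p of camera over 41 lists. A further adjusted p is given where the list was not called with an estimated correlation, and lists without one were called both ways. List calls that are only counted were not made with an estimated correlation.

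The question of BMS-754807 against control was what inhibition of both receptors did without an endocrine agent. SLC26A2, a sulfate transporter, rose by 0.95 ± 0.087 (1.93-fold, adjusted p = 0.00499). The kinase gene SGK3 rose by 0.91 ± 0.13, the monoamine oxidase gene MAOA by 0.83 ± 0.081, IGFBP4, which encodes an IGF-binding protein, by 0.79 ± 0.11, PTGES by 0.75 ± 0.14 and ABHD2 by 0.74 ± 0.12. The transcription factor gene SOX2 fell by 1.02 ± 0.17 and S100A8, a calcium-binding protein of innate immunity, fell by 0.95 ± 0.12. Other large falls were those of IGHG1 (-0.77 ± 0.14), the interferon-induced RSAD2 (-0.73 ± 0.14), KYNU (-0.7 ± 0.087) and IGFBP5 (-0.69 ± 0.12). In limma 78 of 12165 genes changed, 53 higher and 25 lower. Most gene calls ended with any 1 array left out, which lowers precision, or with a plate block. The count was 0 without control replicate 1 (1205 genes at an unadjusted p under 0.05 in limma), 4 without control replicate 2, 5 without BMS-754807 replicate 1 and 4 without BMS-754807 replicate 2. Of the 25 named genes called, 25 calls ended without control replicate 1 (adjusted p 0.0658 to 0.256) and 22 without control replicate 2 (0.0517 to 0.227). Without BMS-754807 replicate 1 and replicate 2, 22 (0.071 to 0.257) and 24 (0.0505 to 0.212) ended. With plate column as a block 34 genes changed. Both BMS-754807 arrays lay in column 6. Medians there against 1 control array were 0.24 (oestrogen-induced), 0.26 (hypoxia) and -0.16 (interferon).

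Of the oestrogen-induced genes, 7 of 42 rose (20 adjusted over the list alone), median 0.27, adjusted p = 4.07e-15. They included GREB1, an oestrogen receptor cofactor (0.63 ± 0.095), CELSR2 (0.54 ± 0.076) and MYC (0.52 ± 0.073). Of the hypoxia genes, 3 of 22 rose and 0 fell (14 and 1 adjusted over the list alone), median 0.24, adjusted p = 2.61e-11. DDIT4, an inhibitor of mTOR signalling, rose by 0.68 ± 0.069 and the angiogenic factor VEGFA by 0.59 ± 0.079. In glycolysis 2 of 19 rose (6 adjusted over the list alone), median 0.12, adjusted p = 1.34e-06, with the enolase gene ENO2 at 0.71 ± 0.085. Of the interferon response genes, 2 of 41 fell (13 adjusted over the list alone), median -0.18, adjusted p = 3.63e-10, with IFIT1 at -0.51 ± 0.088. Of the DNA replication and E2F targets, 0 of 44 passed limma (1 lower adjusted over the list alone, 11 lower and 1 higher at an unadjusted p under 0.05), median -0.09, adjusted p = 9.23e-05. Of the FOXO targets, 1 of 28 rose and 0 fell (6 and 2 adjusted over the list alone), median 0.11, adjusted p = 0.025 and adjusted p = 0.111 with an estimated correlation. The list lost its call without control replicate 1 (adjusted p = 0.151), without BMS-754807 replicate 1 (0.0735) or without BMS-754807 replicate 2 (0.0587). Of the MAPK immediate early genes, 3 of 27 rose and 0 fell (5 and 1 adjusted over the list alone), median 0.12, adjusted p = 0.00307 and adjusted p = 0.0903 with an estimated correlation, with JUN at 0.52 ± 0.072. Of the NRF2 targets, 1 of 17 fell (6 adjusted over the list alone), median -0.06, adjusted p = 0.00293 and adjusted p = 0.0664 with an estimated correlation, with the malic enzyme gene ME1 at -0.45 ± 0.076. In luminal epithelium 0 of 26 passed limma (5 higher adjusted over the list alone, 6 higher at an unadjusted p under 0.05), median 0.06, adjusted p = 0.0085 and adjusted p = 0.13 with an estimated correlation. That call did not hold without control replicate 2 (adjusted p = 0.0592) or without BMS-754807 replicate 2 (0.0708). Of the p53 targets, 0 of 21 passed limma (2 lower adjusted over the list alone, 6 lower at an unadjusted p under 0.05), median -0.16, adjusted p = 0.00293 and adjusted p = 0.0632 with an estimated correlation. In oxidative phosphorylation 0 of 46 passed limma (0 adjusted over the list alone, 4 lower at an unadjusted p under 0.05), median -0.05, adjusted p = 0.000987 and adjusted p = 0.195 with an estimated correlation.

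The mitotic list (median 0.03, adjusted p = 0.574) and the IGF and insulin axis (median 0.03, adjusted p = 0.395) were not called with BMS-754807. IRS2, an adaptor of the insulin receptor, rose by 0.52 ± 0.085, a call that ended without control replicate 1 (adjusted p = 0.213), without control replicate 2 (0.111), without BMS-754807 replicate 1 (0.127) or without BMS-754807 replicate 2 (0.199). MKI67, a proliferation marker, differed by 0.19 ± 0.078 (adjusted p = 0.351) and ESR1, the oestrogen receptor gene, by 0.31 ± 0.066 (adjusted p = 0.0747). The differences of PGR (0.23 ± 0.15), TFF1 (-0.02 ± 0.061), IGF1R (0.3 ± 0.18), INSR (0.17 ± 0.098), IRS1 (0.18 ± 0.081), ERBB3 (0.22 ± 0.067) and CCND1 (0.54 ± 0.11) did not pass. INSR lay at 2.89 in control, close to the lowest values of the arrays.

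Tamoxifen against control asked what the oestrogen receptor modulator did alone. CALML5, a calmodulin-like protein of differentiating epidermis, rose by 5.17 ± 0.11 (35.9-fold, adjusted p = 4.59e-10). MSMB, a secreted prostate protein, rose by 4.74 ± 0.093, the efflux transporter gene ABCC4 by 4.67 ± 0.084, the kallikrein gene KLK11 by 4.42 ± 0.12, the keratin gene KRT13 by 4.37 ± 0.11 and SYBU by 4.35 ± 0.17. NPY1R, a neuropeptide Y receptor, fell by 4.79 ± 0.12 (27.8-fold, adjusted p = 2.27e-09). Next came the fatty acid elongase gene ELOVL2 (-3.39 ± 0.089), DLC1, which encodes a Rho GTPase-activating protein (-2.98 ± 0.15), CLSTN2 (-2.78 ± 0.13), JAM2 (-2.77 ± 0.16) and the angiotensin receptor gene AGTR1 (-2.7 ± 0.18). In limma 2692 genes changed, 1267 higher and 1425 lower, of which 192 and 81 by at least 2-fold.

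Proliferation genes fell with tamoxifen. Of the mitotic genes, 36 of 39 fell (37 adjusted over the list alone), median -0.66, adjusted p = 2.01e-25. The cyclin gene CCNB2 fell by 0.91 ± 0.065, TTK, a spindle checkpoint kinase, fell by 0.93 ± 0.079 and MKI67 fell by 0.57 ± 0.078. Within plate columns 5 and 6, with 1 array against 1, the mitotic medians were -0.65 and -0.66. Among the DNA replication and E2F targets, 34 of 44 fell (38 adjusted over the list alone), median -0.6, adjusted p = 1.03e-19, with MCM10 at -1.37 ± 0.1. In ribosome biogenesis 16 of 29 fell (18 adjusted over the list alone), median -0.26, adjusted p = 1.58e-06, with RRS1 at -0.54 ± 0.072.

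Among the oestrogen-induced genes, 24 of 42 fell and 7 rose (24 and 8 adjusted over the list alone), median -0.48, adjusted p = 0.000178 with tamoxifen. RAB31 (-2.59 ± 0.13) and the carbonic anhydrase gene CA12 (-2.5 ± 0.11) were among those that fell, and KRT13 rose as given above. GREB1 fell by 1.24 ± 0.095, PGR, the progesterone receptor gene, fell by 0.77 ± 0.15, TFF1 fell by 0.48 ± 0.061 and ESR1 fell by 0.78 ± 0.066. IGF1R, which encodes a target of BMS-754807, fell by 2.42 ± 0.18 (adjusted p = 4.31e-06). ERBB3, a HER family receptor, rose by 0.68 ± 0.067. INSR (-0.09 ± 0.098), IRS1 (0.21 ± 0.081), IRS2 (-0.25 ± 0.085) and CCND1 (-0.14 ± 0.11) did not pass. Of the androgen receptor targets, 7 of 18 rose and 1 fell (8 and 1 adjusted over the list alone), median 0.1, adjusted p = 0.000579. PIP, a secreted apocrine protein, rose by 3.77 ± 0.19 and UGT2B28 by 2.83 ± 0.091. FKBP5, at -0.43 ± 0.11, lost its call without control replicate 1 (adjusted p = 0.0955), without control replicate 2 (0.0676) or without Tamoxifen replicate 1 (0.103). In autophagy and lysosome 9 of 27 rose (9 adjusted over the list alone), median 0.15, adjusted p = 0.000771, with WIPI1 at 1.76 ± 0.076.

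Among the interferon response genes, 13 of 41 rose and 1 fell (15 and 1 adjusted over the list alone), median 0.18, adjusted p = 0.000771 and adjusted p = 0.16 with an estimated correlation, with IRF9 at 0.72 ± 0.079. In class I antigen presentation 6 of 14 rose (8 adjusted over the list alone), median 0.29, adjusted p = 0.000588 and adjusted p = 0.161 with an estimated correlation, with HLA-B at 0.55 ± 0.066. Probe sets of near-identical pairs such as HLA-B and HLA-C, SERHL and SERHL2, or HBG1 and HBG2 can report either gene. Of the oestrogen-repressed genes, 9 of 19 rose and 3 fell (10 and 3 adjusted over the list alone), median 0.2, adjusted p = 0.00871 and adjusted p = 0.0802 with an estimated correlation, with BIK, a pro-apoptotic gene, at 1.69 ± 0.074. In heat shock 7 of 16 fell (7 adjusted over the list alone), median -0.11, adjusted p = 0.00226 and adjusted p = 0.0567 with an estimated correlation, with the co-chaperone FKBP4 at -0.85 ± 0.073. Of the differentiation and milk genes, 6 of 20 rose and 3 fell (6 and 3 adjusted over the list alone), median 0.09, adjusted p = 0.0332 and adjusted p = 0.249 with an estimated correlation, with the transcription factor ELF5 at 2.61 ± 0.084. Of the erythroid markers, 1 of 8 rose (1 adjusted over the list alone), median 0.43, adjusted p = 0.0327 and adjusted p = 0.295 with an estimated correlation. This call ended without control replicate 1 (adjusted p = 0.0714) or without Tamoxifen replicate 1 (0.437). HBB read 8.92 and HBA2 9.52 on Tamoxifen replicate 1, against 3.82 and 5.73 on Tamoxifen replicate 2. In the p53 list 9 of 21 fell and 1 rose (9 and 2 adjusted over the list alone), median -0.23, adjusted p = 0.0368 and adjusted p = 0.149 with an estimated correlation. That call was lost without control replicate 1 (adjusted p = 0.0919) or without Tamoxifen replicate 2 (0.0781).

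Letrozole against control asked what the aromatase inhibitor did alone. PIP rose by 3.61 ± 0.19 (12.2-fold, adjusted p = 1.89e-06). SERHL rose by 3.58 ± 0.082, SERHL2 by 3.49 ± 0.088, the carboxypeptidase gene CPB1 by 2.87 ± 0.18, CRAT, a carnitine acetyltransferase, by 2.79 ± 0.17 and CEACAM7 by 2.63 ± 0.15. PDZK1, a scaffold protein gene, fell by 2.11 ± 0.11 (4.31-fold, adjusted p = 1.89e-06). RAB31 (-1.68 ± 0.13), ELOVL2 (-1.63 ± 0.089), NPY1R (-1.6 ± 0.12), the matrix Gla protein gene MGP (-1.57 ± 0.076) and PLAC1 (-1.56 ± 0.084) followed. In limma 1336 genes changed, 684 higher and 652 lower, of which 70 and 33 by at least 2-fold. The count was 735 without control replicate 1, 661 without control replicate 2, 710 without Letrozole replicate 1 and 666 without Letrozole replicate 2.

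For the interferon response genes, 31 of 41 rose and 0 fell (34 and 1 adjusted over the list alone), median 0.53, adjusted p = 2.11e-29 with letrozole. PSMB9, an immunoproteasome subunit, rose by 1.48 ± 0.1, UBE2L6 by 1.16 ± 0.085 and IFIT1 by 1 ± 0.088. Within plate columns 5 and 6 the interferon medians were 0.53 and 0.54. In class I antigen presentation 9 of 14 rose (12 adjusted over the list alone), median 0.39, adjusted p = 3.75e-11, with the peptide transporter TAP1 at 1.02 ± 0.11. Among the mitotic genes, 32 of 39 fell (36 adjusted over the list alone), median -0.4, adjusted p = 5.32e-24, with TTK at -0.73 ± 0.079. For the DNA replication and E2F targets, 30 of 44 fell (36 adjusted over the list alone), median -0.44, adjusted p = 1.16e-21, with CDC45 at -0.72 ± 0.072. In ribosome biogenesis 10 of 29 fell (20 adjusted over the list alone), median -0.24, adjusted p = 1.21e-09. Among the hypoxia genes, 7 of 22 rose (8 adjusted over the list alone), median 0.2, adjusted p = 0.000426, with adrenomedullin (ADM) at 0.78 ± 0.098.

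For the oestrogen-induced genes, 25 of 42 fell and 2 rose (26 and 3 adjusted over the list alone), median -0.54, adjusted p = 2.52e-17 with letrozole. CELSR2 (-1.35 ± 0.076) and TPD52L1 (-1.08 ± 0.062) fell, and STC2, a secreted glycoprotein, rose by 0.65 ± 0.086. GREB1 fell by 1.32 ± 0.095 and PGR fell by 1.13 ± 0.15, whereas ESR1 rose by 0.54 ± 0.066 (adjusted p = 0.000437). Among the oestrogen-repressed genes, 10 of 19 rose and 1 fell (11 and 2 adjusted over the list alone), median 0.39, adjusted p = 2.43e-05, with the interleukin-1 receptor gene IL1R1 at 1.9 ± 0.13. Among the androgen receptor targets, 7 of 18 rose (7 adjusted over the list alone), median 0.17, adjusted p = 8.91e-06, with AZGP1 at 1.77 ± 0.084. In luminal epithelium 9 of 26 rose and 1 fell (9 and 2 adjusted over the list alone), median 0.13, adjusted p = 0.000203, with the mucin gene MUC1 at 1.26 ± 0.083. Among the FOXO targets, 9 of 28 rose and 0 fell (12 and 1 adjusted over the list alone), median 0.13, adjusted p = 0.00032, with the death ligand TNFSF10 at 2.29 ± 0.17 and ERBB3 at 0.43 ± 0.067. In the TGF-beta response 4 of 19 rose and 1 fell (4 and 1 adjusted over the list alone), median 0.14, adjusted p = 0.021 and adjusted p = 0.0846 with an estimated correlation. The list lost its call without control replicate 2 (adjusted p = 0.0938). In endoplasmic reticulum stress 5 of 19 rose (5 adjusted over the list alone), median 0.08, adjusted p = 0.0427 and adjusted p = 0.115 with an estimated correlation. Its call ended without control replicate 2 (adjusted p = 0.0931) or without Letrozole replicate 2 (0.0757).

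TFF1 (-0.27 ± 0.061), IGF1R (-0.7 ± 0.18), IRS1 (-0.38 ± 0.081), IRS2 (0.37 ± 0.085) and MKI67 (-0.38 ± 0.078) also passed with letrozole, but not without every array. The call of TFF1 ended without control replicate 1 (adjusted p = 0.0707), without control replicate 2 (0.0902), without Letrozole replicate 1 (0.0771) or without Letrozole replicate 2 (0.0922). That of IGF1R ended without control replicate 1 (adjusted p = 0.084), without control replicate 2 (0.156) or without Letrozole replicate 1 (0.207). That of IRS1 ended without control replicate 2 (adjusted p = 0.106) or without Letrozole replicate 1 (0.101). For IRS2 it ended without control replicate 1 (adjusted p = 0.124), without control replicate 2 (0.0578), without Letrozole replicate 1 (0.105) or without Letrozole replicate 2 (0.0824). For MKI67 it ended without control replicate 1 (adjusted p = 0.0522), without control replicate 2 (0.0725) or without Letrozole replicate 1 (0.0986). INSR (0 ± 0.098) and CCND1 (-0.11 ± 0.11) did not pass.

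Tamoxifen with BMS-754807 against control asked what this combination did. CALML5 rose by 5.86 ± 0.11 (57.9-fold, adjusted p = 1.25e-10). CCNO, a cyclin-like gene of multiciliated cells, rose by 5.29 ± 0.11, PIP by 5.03 ± 0.19, MSMB by 4.95 ± 0.093, SYBU by 4.92 ± 0.17 and the kallikrein gene KLK13 by 4.9 ± 0.13. NPY1R fell by 4.87 ± 0.12 and ELOVL2 fell by 4.29 ± 0.089, ahead of DLC1 (-3.72 ± 0.15), CLSTN2 (-3.14 ± 0.13), RAB31 (-3.11 ± 0.13) and the protease inhibitor gene SERPINA3 (-2.93 ± 0.12). In limma 3635 genes changed, 1674 higher and 1961 lower, of which 303 and 202 by at least 2-fold.

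For the mitotic genes, 37 of 39 fell (38 adjusted over the list alone), median -1.28, adjusted p = 1.51e-30 with this combination. MKI67 fell by 1.4 ± 0.078 (adjusted p = 2.83e-07) and KIF2C fell by 1.66 ± 0.074. Within plate columns 5 and 6 the mitotic medians were -1.26 and -1.27. Of the DNA replication and E2F targets, 38 of 44 fell (41 adjusted over the list alone), median -0.99, adjusted p = 7.43e-25, with MCM10 at -2.16 ± 0.1. In ribosome biogenesis 24 of 29 fell (25 adjusted over the list alone), median -0.49, adjusted p = 9.09e-10. Of the oestrogen-induced genes, 27 of 42 fell and 6 rose (27 and 7 adjusted over the list alone), median -0.54, adjusted p = 1.08e-05, with GREB1 at -0.68 ± 0.095 and TFF1 at -0.6 ± 0.061. For the androgen receptor targets, 9 of 18 rose (10 adjusted over the list alone), median 0.46, adjusted p = 4.06e-06, with UGT2B28 at 4.08 ± 0.091. For the hypoxia genes, 14 of 22 rose (14 adjusted over the list alone), median 0.33, adjusted p = 9e-05, with ADM at 2.93 ± 0.098 and NDRG1 at 1.48 ± 0.12. In the interferon response 22 of 41 rose and 3 fell (24 and 3 adjusted over the list alone), median 0.37, adjusted p = 4.06e-06 and adjusted p = 0.0593 with an estimated correlation. In class I antigen presentation 9 of 14 rose and 0 fell (10 and 1 adjusted over the list alone), median 0.38, adjusted p = 0.000444 and adjusted p = 0.151 with an estimated correlation. Among the p53 targets, 12 of 21 fell and 1 rose (12 and 1 adjusted over the list alone), median -0.32, adjusted p = 0.00387 and adjusted p = 0.0593 with an estimated correlation. In autophagy and lysosome 12 of 27 rose and 2 fell (12 and 2 adjusted over the list alone), median 0.18, adjusted p = 0.00313 and adjusted p = 0.0593 with an estimated correlation. Among the differentiation and milk genes, 8 of 20 rose and 2 fell (9 and 2 adjusted over the list alone), median 0.16, adjusted p = 0.000676 and adjusted p = 0.0866 with an estimated correlation, with ELF5 at 2.66 ± 0.084.

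ESR1 fell by 0.73 ± 0.066, IGF1R fell by 2.5 ± 0.18 and IRS2 fell by 0.41 ± 0.085 with this combination, ERBB3 rose by 0.84 ± 0.067, and INSR (-0.01 ± 0.098) did not pass. PGR, at -0.53 ± 0.15, lost its call without control replicate 2 (adjusted p = 0.154) or without Tamoxifen+BMS-754807 replicate 1 (0.145). IRS1, at 0.27 ± 0.081, lost it without control replicate 1 (adjusted p = 0.189) or without Tamoxifen+BMS-754807 replicate 1 (0.147). CCND1, at -0.36 ± 0.11, lost it without control replicate 1 (adjusted p = 0.0881), without control replicate 2 (0.133), without Tamoxifen+BMS-754807 replicate 1 (0.086) or without Tamoxifen+BMS-754807 replicate 2 (0.129). Oestrogen-repressed genes were not called (adjusted p = 0.145), and their median of -0.01 and mean of 0.39 differed in sign.

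Letrozole with BMS-754807 against control asked the same of the other combination. CPB1 rose by 3.48 ± 0.18 (11.1-fold, adjusted p = 1.36e-06). SERHL rose by 3.42 ± 0.082, SERHL2 by 3.33 ± 0.088, PIP by 3.01 ± 0.19, CRAT by 2.68 ± 0.17 and IGHG1, an immunoglobulin heavy chain gene, by 2.57 ± 0.14. PDZK1 fell by 1.96 ± 0.11 and PLAC1 fell by 1.84 ± 0.084, followed by MGP (-1.8 ± 0.076), GREB1 (-1.79 ± 0.095), TMPRSS3 (-1.79 ± 0.093) and ELOVL2 (-1.76 ± 0.089). In limma 1733 genes changed, 873 higher and 860 lower. The count was 959 without control replicate 1, 948 without control replicate 2, 1042 without Letrozole+BMS-754807 replicate 1 and 950 without Letrozole+BMS-754807 replicate 2.

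Among the DNA replication and E2F targets, 35 of 44 fell (39 adjusted over the list alone), median -0.54, adjusted p = 3.03e-24 with this combination, and CDC45 was at -1.04 ± 0.072. Of the mitotic genes, 30 of 39 fell (36 adjusted over the list alone), median -0.38, adjusted p = 5.83e-20. Among the oestrogen-induced genes, 28 of 42 fell and 5 rose (30 and 5 adjusted over the list alone), median -0.52, adjusted p = 4.01e-14, with TPD52L1 at -1.22 ± 0.062. PGR fell by 1.24 ± 0.15, TFF1 fell by 0.42 ± 0.061 and ESR1 rose by 0.81 ± 0.066. Of the interferon response genes, 20 of 41 rose and 1 fell (26 and 1 adjusted over the list alone), median 0.33, adjusted p = 1.73e-12, with UBE2L6 at 1.05 ± 0.085. Within plate column 6 (2 arrays against 1) the medians were -0.52, -0.36, -0.58 and 0.35 for these 4 lists. In ribosome biogenesis 10 of 29 fell (16 adjusted over the list alone), median -0.25, adjusted p = 1.39e-08. For the oestrogen-repressed genes, 10 of 19 rose and 1 fell (11 and 2 adjusted over the list alone), median 0.4, adjusted p = 3.74e-06. Of the androgen receptor targets, 7 of 18 rose and 1 fell (7 and 1 adjusted over the list alone), median 0.09, adjusted p = 0.000549. In class I antigen presentation 8 of 14 rose (10 adjusted over the list alone), median 0.35, adjusted p = 1.85e-06 and adjusted p = 0.0637 with an estimated correlation. In luminal epithelium 8 of 26 rose and 3 fell (10 and 3 adjusted over the list alone), median 0.13, adjusted p = 0.000327 and adjusted p = 0.0569 with an estimated correlation. For the FOXO targets, 8 of 28 rose and 2 fell (11 and 2 adjusted over the list alone), median 0.19, adjusted p = 0.00842 and adjusted p = 0.0637 with an estimated correlation. In cholesterol biosynthesis 6 of 20 fell and 3 rose (10 and 4 adjusted over the list alone), median -0.21, adjusted p = 0.00842 and adjusted p = 0.12 with an estimated correlation, with the isomerase gene EBP at -0.54 ± 0.067. Of the ATF4 targets, 8 of 30 fell and 1 rose (11 and 1 adjusted over the list alone), median -0.09, adjusted p = 0.0185 and adjusted p = 0.073 with an estimated correlation. That call did not hold without Letrozole+BMS-754807 replicate 1 (adjusted p = 0.0606). In the IGF and insulin axis 6 of 21 rose and 3 fell (7 and 3 adjusted over the list alone), median 0.06, adjusted p = 0.0462 and adjusted p = 0.234 with an estimated correlation, with IGFBP5 at 1.08 ± 0.12. This call ended without control replicate 2 (adjusted p = 0.0781) or without Letrozole+BMS-754807 replicate 2 (0.106). In the TGF-beta list 3 of 19 rose (3 adjusted over the list alone), median 0.12, adjusted p = 0.0462 and adjusted p = 0.124 with an estimated correlation. That call was lost without control replicate 2 (adjusted p = 0.135), without Letrozole+BMS-754807 replicate 1 (0.0528) or without Letrozole+BMS-754807 replicate 2 (0.0629).

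IRS2 rose by 0.47 ± 0.085 and ERBB3 by 0.56 ± 0.067 with this combination, and INSR (0.05 ± 0.098) did not pass. IGF1R, at -0.59 ± 0.18, lost its call without control replicate 1 (adjusted p = 0.113), without control replicate 2 (0.213), without Letrozole+BMS-754807 replicate 1 (0.0973) or without Letrozole+BMS-754807 replicate 2 (0.235). The call of IRS1 (-0.36 ± 0.081) ended without control replicate 2 (adjusted p = 0.112), without Letrozole+BMS-754807 replicate 1 (0.0849) or without Letrozole+BMS-754807 replicate 2 (0.0523). That of CCND1 (0.51 ± 0.11) ended without control replicate 1 (adjusted p = 0.0726), without control replicate 2 (0.053) or without Letrozole+BMS-754807 replicate 2 (0.0564). That of MKI67 (-0.38 ± 0.078) ended without control replicate 2 (adjusted p = 0.0607) or without Letrozole+BMS-754807 replicate 1 (0.075).

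**Figure D2:**
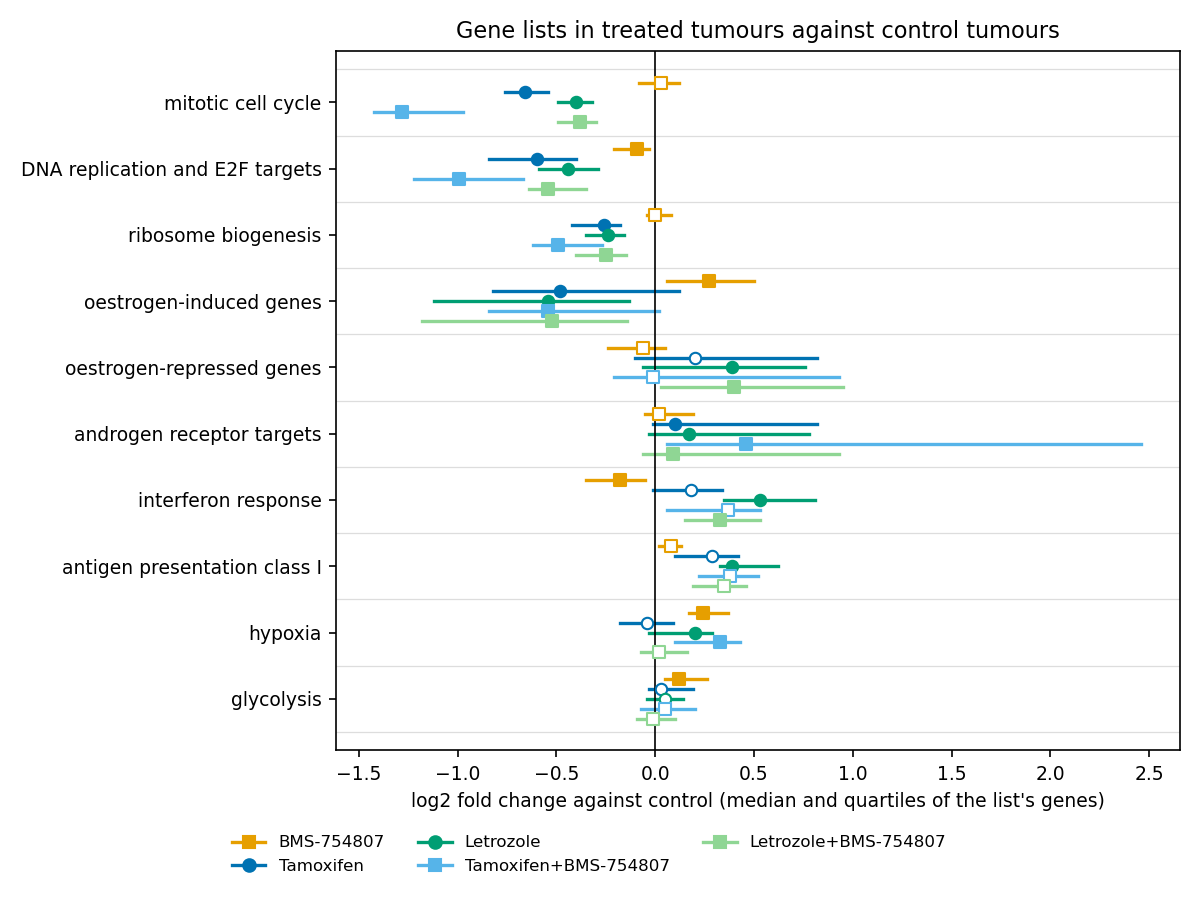
Log2 fold change against control of 10 gene lists (vertical) in the 5 treated groups, where points are list medians, bars run from the lower to the upper quartile of the list's genes, and filled points are lists called by camera with the preset and with an estimated correlation. The mitotic medians run from 0.03 with BMS-754807 to -1.28 with Tamoxifen+BMS-754807, and the interferon response medians from -0.18 with BMS-754807 to 0.53 with Letrozole.

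What BMS-754807 added to tamoxifen was read from the combination against Tamoxifen. KLK3, which encodes prostate-specific antigen, rose by 2.27 ± 0.1 (4.83-fold, adjusted p = 1.96e-06). ZBBX rose by 1.99 ± 0.15, and DNAI7 (1.9 ± 0.16) and ZMYND10 (1.84 ± 0.27), genes of motile cilia, rose too. IGHG1 fell by 3.91 ± 0.14, ahead of the Ras activator gene RASGRP1 (-1.51 ± 0.11), SCUBE2 (-1.32 ± 0.076) and PDZK1 (-1.22 ± 0.11). In limma 1063 genes changed, 514 higher and 549 lower. The count was 575 without Tamoxifen replicate 2, 550 without Tamoxifen+BMS-754807 replicate 1 and 569 without Tamoxifen+BMS-754807 replicate 2. It was 279 with a minimum of 1.5-fold, where more were higher (172) than lower (107), and 271 in a fit to the compared groups alone (151 and 120).

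Among the mitotic genes, 31 of 39 fell (31 adjusted over the list alone), median -0.54, adjusted p = 1.08e-26 below tamoxifen alone. The kinase PLK1 was at -0.9 ± 0.072 and MKI67 at -0.83 ± 0.078. Within plate columns 5 and 6 the mitotic medians were -0.62 and -0.5. For the DNA replication and E2F targets, 27 of 44 fell (33 adjusted over the list alone), median -0.42, adjusted p = 7.54e-20. Of the hypoxia genes, 9 of 22 rose (15 adjusted over the list alone), median 0.31, adjusted p = 1.26e-09, with NDRG1 at 0.93 ± 0.12. Among the androgen receptor targets, 7 of 18 rose (8 adjusted over the list alone), median 0.16, adjusted p = 1.05e-05, with AZGP1 at 1.33 ± 0.084. In ribosome biogenesis 3 of 29 fell (15 adjusted over the list alone), median -0.2, adjusted p = 2.69e-05. For the differentiation and milk genes, 6 of 20 rose (7 adjusted over the list alone), median 0.16, adjusted p = 0.000153 and adjusted p = 0.0785 with an estimated correlation. In the interferon response 8 of 41 rose and 1 fell (11 and 1 adjusted over the list alone), median 0.13, adjusted p = 0.000474 and adjusted p = 0.14 with an estimated correlation, and IRF1 fell by 0.53 ± 0.079. In heat shock 5 of 16 rose (6 adjusted over the list alone), median 0.11, adjusted p = 0.00611 and adjusted p = 0.0785 with an estimated correlation. In fatty acid synthesis 3 of 17 fell and 1 rose (4 and 1 adjusted over the list alone), median -0.08, adjusted p = 0.0444 and adjusted p = 0.443 with an estimated correlation, with ME1 at -0.76 ± 0.076. The list lost its call without Tamoxifen replicate 1 (adjusted p = 0.146) or without Tamoxifen+BMS-754807 replicate 1 (0.244). In the p53 list 2 of 21 fell and 0 rose (8 and 2 adjusted over the list alone), median -0.18, adjusted p = 0.0173 and adjusted p = 0.0989 with an estimated correlation. It lost its call without Tamoxifen replicate 1 (adjusted p = 0.13) or without Tamoxifen+BMS-754807 replicate 2 (0.0588). In the oestrogen-induced list 8 of 42 fell and 3 rose (8 and 3 adjusted over the list alone), median -0.1, adjusted p = 0.0396 and adjusted p = 0.13 with an estimated correlation. Its call ended without Tamoxifen replicate 1 (adjusted p = 0.146) or without Tamoxifen+BMS-754807 replicate 1 (0.0923).

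What BMS-754807 added to letrozole was read in the same way. IGHG1 rose by 2.54 ± 0.14 (5.8-fold, adjusted p = 2.73e-05), GUSBP1, a pseudogene, by 1.34 ± 0.13 and GOLGA8A by 0.95 ± 0.094. The other probe sets naming IGHG1 alone lay between 2.96 and 3.79 in every group, near the floor. KMO, a kynurenine monooxygenase, fell by 1.45 ± 0.13 and HBG1, a fetal haemoglobin gene, fell by 1 ± 0.068. NELL2, at 0.91 ± 0.12, lost its call without Letrozole replicate 1 (adjusted p = 0.0631), without Letrozole replicate 2 (0.109), without Letrozole+BMS-754807 replicate 1 (0.099) or without Letrozole+BMS-754807 replicate 2 (0.0997). TNFSF10, at -1.46 ± 0.17, lost it without Letrozole replicate 2 (adjusted p = 0.0992), without Letrozole+BMS-754807 replicate 1 (0.0505) or without Letrozole+BMS-754807 replicate 2 (0.0918). In limma 91 genes changed, 48 higher and 43 lower. The count was 16 without Letrozole replicate 1, 6 without Letrozole replicate 2, 7 without Letrozole+BMS-754807 replicate 1 and 9 without Letrozole+BMS-754807 replicate 2. With plate column as a block it was 30.

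Among the interferon response genes, 5 of 41 fell (21 adjusted over the list alone), median -0.26, adjusted p = 5.91e-15 below letrozole alone. Within plate column 6 (2 arrays against 1) the interferon median was -0.24. Among the NRF2 targets, 2 of 17 fell (7 adjusted over the list alone), median -0.18, adjusted p = 4.36e-06. In endoplasmic reticulum stress 3 of 19 fell (6 adjusted over the list alone), median -0.13, adjusted p = 8.28e-05. The mitotic list, with a median of 0, was not called (adjusted p = 0.831). In class I antigen presentation 1 of 14 fell (3 adjusted over the list alone), median -0.17, adjusted p = 0.00208 and adjusted p = 0.238 with an estimated correlation. Of the DNA replication and E2F targets, 0 of 44 passed limma (1 lower adjusted over the list alone, 10 lower at an unadjusted p under 0.05), median -0.06, adjusted p = 0.00302 and adjusted p = 0.0854 with an estimated correlation. In the hypoxia list 2 of 22 fell (4 adjusted over the list alone), median -0.06, adjusted p = 0.00696 and adjusted p = 0.127 with an estimated correlation. It lost its call without Letrozole replicate 2 (adjusted p = 0.0529). In the ATF4 list 2 of 30 fell and 0 rose (3 and 1 adjusted over the list alone), median -0.08, adjusted p = 0.00696 and adjusted p = 0.0902 with an estimated correlation. Its call ended without Letrozole+BMS-754807 replicate 1 (adjusted p = 0.119). In cholesterol biosynthesis 0 of 20 passed limma (0 adjusted over the list alone, 5 lower at an unadjusted p under 0.05), median -0.1, adjusted p = 0.00696 and adjusted p = 0.178 with an estimated correlation. It lost its call without Letrozole+BMS-754807 replicate 1 (adjusted p = 0.119). In the IGF and insulin axis 0 of 21 passed limma (0 adjusted over the list alone, 7 higher at an unadjusted p under 0.05), median 0.11, adjusted p = 0.00613 and adjusted p = 0.206 with an estimated correlation. Its call ended without Letrozole replicate 2 (adjusted p = 0.0655).

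**Figure D3:**
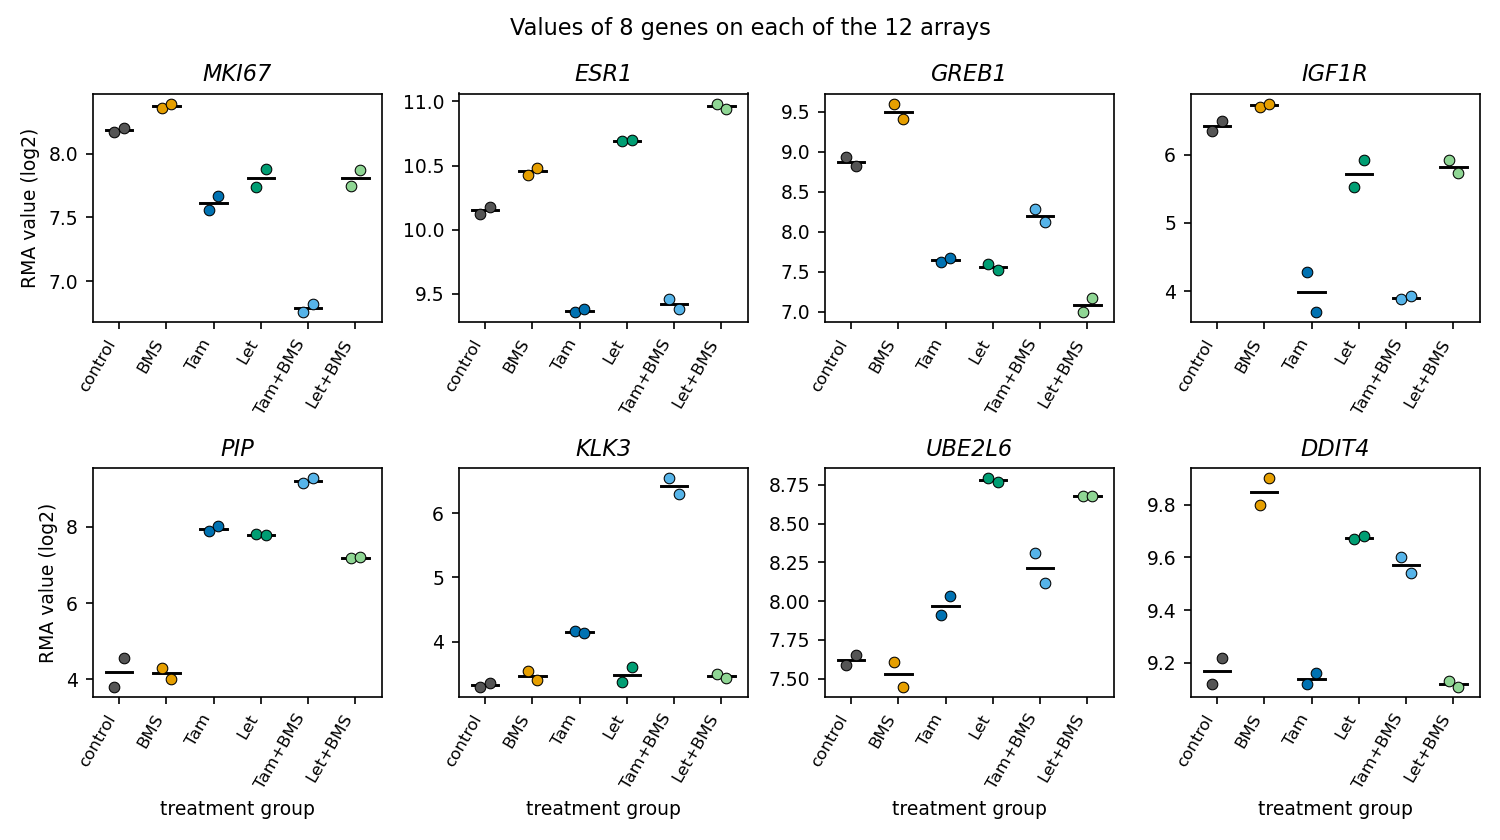
RMA values (log2, vertical, each panel on its own scale) of 8 genes on the 12 arrays by treatment group (horizontal), with 1 point per array and a line at the mean of the 2 arrays. MKI67 is lowest with Tamoxifen+BMS-754807, at a mean of 6.79, and KLK3 is highest there, at 6.42.

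Whether BMS-754807 acted differently with tamoxifen was tested as an interaction, its effect on tamoxifen minus that without it. It was 2.13 ± 0.14 for KLK3 (adjusted p = 5e-05), near the floor without tamoxifen. It was 2.16 ± 0.17 for S100A8 and 1.95 ± 0.22 for ZBBX. It was -3.14 ± 0.19 for IGHG1, -2.12 ± 0.16 for RASGRP1, -1.73 ± 0.11 for SCUBE2, -1.34 ± 0.13 for ELOVL2 and -1.01 ± 0.11 for MKI67. ZMYND10, at 1.92 ± 0.38, lost its call without control replicate 1 (adjusted p = 0.0656), without control replicate 2 (0.0789), without BMS-754807 replicate 1 (0.0793), without BMS-754807 replicate 2 (0.0598) or without Tamoxifen+BMS-754807 replicate 2 (0.0792). The interaction passed in limma for 386 genes, 186 positive and 200 negative. The count was 193 without control replicate 1, 235 without control replicate 2, 213 without BMS-754807 replicate 1 and 201 without BMS-754807 replicate 2.

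For the mitotic genes, 22 of 39 were negative (31 adjusted over the list alone), median -0.55, adjusted p = 2.57e-25 for the interaction with tamoxifen. Among the DNA replication and E2F targets, 6 of 44 were negative and 0 positive (19 and 1 adjusted over the list alone), median -0.35, adjusted p = 2.07e-10. For the oestrogen-induced genes, 12 of 42 were negative and 1 positive (22 and 1 adjusted over the list alone), median -0.4, adjusted p = 1.06e-11, with PDZK1 at -1.29 ± 0.15. For the androgen receptor targets, 6 of 18 were positive and 0 negative (8 and 1 adjusted over the list alone), median 0.34, adjusted p = 3.23e-05. For the interferon response genes, 7 of 41 were positive and 0 negative (23 and 1 adjusted over the list alone), median 0.34, adjusted p = 3.33e-11, with IFIT1 at 0.9 ± 0.12. In ribosome biogenesis 1 of 29 was negative (6 adjusted over the list alone), median -0.14, adjusted p = 0.000342. Of the differentiation and milk genes, 5 of 20 were positive (6 adjusted over the list alone), median 0.07, adjusted p = 0.00215 and adjusted p = 0.158 with an estimated correlation. In the MAPK list 5 of 27 were negative and 1 positive (5 and 1 adjusted over the list alone), median -0.15, adjusted p = 0.0258 and adjusted p = 0.207 with an estimated correlation. It lost its call without control replicate 1 (adjusted p = 0.0782), without BMS-754807 replicate 1 (0.0641) or without Tamoxifen replicate 2 (0.167). In fatty acid synthesis 1 of 17 was negative and 0 positive (6 and 1 adjusted over the list alone), median -0.18, adjusted p = 0.0178 and adjusted p = 0.402 with an estimated correlation. That call was lost without BMS-754807 replicate 1 (adjusted p = 0.0641), without Tamoxifen replicate 1 (0.0712) or without Tamoxifen+BMS-754807 replicate 1 (0.0927). In glycolysis 0 of 19 passed limma (1 negative adjusted over the list alone, 4 negative at an unadjusted p under 0.05), median -0.14, adjusted p = 0.0178 and adjusted p = 0.244 with an estimated correlation. That call was lost without Tamoxifen replicate 2 (adjusted p = 0.0812). BMS-754807 had no array in plate column 5, so the interaction had no value there. With plate column as a block it passed for 282 genes.

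The interaction with letrozole passed in limma for 19 genes, 6 positive and 13 negative. It was 3.3 ± 0.19 for IGHG1 (adjusted p = 6.27e-05) and -1.23 ± 0.097 for DDIT4 (adjusted p = 0.000701). IGFBP5 (1.17 ± 0.17), CYP26A1, a retinoic acid hydroxylase (1.04 ± 0.15), KYNU (1.01 ± 0.12), SGK3 (-1.26 ± 0.19), GREB1 (-1.1 ± 0.13) and PLAC1 (-1.01 ± 0.12) also passed. Of the 11 named genes called, IGHG1 and DDIT4 held without any 1 of the 8 arrays. The calls that ended were 9 without control replicate 1 (adjusted p 0.0543 to 0.17), 8 without control replicate 2 (0.0788 to 0.133), 9 without BMS-754807 replicate 1 (0.0913 to 0.142) and 6 without BMS-754807 replicate 2 (0.0537 to 0.151). They were 9 each without Letrozole replicate 1 (0.0773 to 0.137) or 2 (0.0515 to 0.195) and without Letrozole+BMS-754807 replicate 1 (0.0701 to 0.181) or 2 (0.0595 to 0.143). The count was 3 without control replicate 1, control replicate 2 or BMS-754807 replicate 1, 9 without BMS-754807 replicate 2, and 2 without Letrozole replicate 1 or 2 or Letrozole+BMS-754807 replicate 1 or 2. With plate column as a block it was 11.

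Among the hypoxia genes, 2 of 22 were negative (15 adjusted over the list alone), median -0.4, adjusted p = 1.27e-13 for the interaction with letrozole. Of the oestrogen-induced genes, 2 of 42 were negative and 0 positive (13 and 1 adjusted over the list alone), median -0.28, adjusted p = 3.77e-10. In endoplasmic reticulum stress 0 of 19 passed limma (4 negative adjusted over the list alone, 6 negative at an unadjusted p under 0.05), median -0.15, adjusted p = 7.75e-05. In glycolysis 1 of 19 was negative (5 adjusted over the list alone), median -0.19, adjusted p = 4e-06 and adjusted p = 0.0561 with an estimated correlation. Of the FOXO targets, 1 of 28 was negative (2 adjusted over the list alone), median -0.1, adjusted p = 0.00634 and adjusted p = 0.0776 with an estimated correlation. In class I antigen presentation 0 of 14 passed limma (5 negative adjusted over the list alone, 5 negative at an unadjusted p under 0.05), median -0.22, adjusted p = 7.75e-05 and adjusted p = 0.128 with an estimated correlation. In heat shock 0 of 16 passed limma (2 negative adjusted over the list alone, 4 negative at an unadjusted p under 0.05), median -0.13, adjusted p = 0.00346 and adjusted p = 0.0776 with an estimated correlation. In the androgen receptor list 0 of 18 passed limma (2 negative adjusted over the list alone, 4 negative and 2 positive at an unadjusted p under 0.05), median -0.14, adjusted p = 0.0319 and adjusted p = 0.128 with an estimated correlation. Its call ended without control replicate 1 (adjusted p = 0.102), without BMS-754807 replicate 1 (0.0608), without Letrozole replicate 2 (0.055) or without Letrozole+BMS-754807 replicate 1 (0.16). In cholesterol biosynthesis 0 of 20 passed limma (0 adjusted over the list alone, 2 negative at an unadjusted p under 0.05), median -0.11, adjusted p = 0.0211 and adjusted p = 0.188 with an estimated correlation. It lost its call without control replicate 2 (adjusted p = 0.136), without BMS-754807 replicate 2 (0.0515), without Letrozole replicate 2 (0.055) or without Letrozole+BMS-754807 replicate 1 (0.144). In the oestrogen-repressed list 0 of 19 passed limma (2 positive adjusted over the list alone, 2 positive at an unadjusted p under 0.05), median 0.06, adjusted p = 0.0211 and adjusted p = 0.127 with an estimated correlation. That call was lost without control replicate 2 (adjusted p = 0.059), without BMS-754807 replicate 2 (0.0515), without Letrozole replicate 1 (0.103) or without Letrozole+BMS-754807 replicate 2 (0.0556).

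Averaged over the 3 backgrounds, 6 arrays with BMS-754807 against 6 without, CPB1 rose by 0.91 ± 0.1 (adjusted p = 0.00167), KLK3 by 0.8 ± 0.058, DNAI7 by 0.72 ± 0.091 and the cyclin gene CCNA1 by 0.7 ± 0.11. IGHG1 (-0.71 ± 0.078), HBG1 (-0.65 ± 0.039), ME1 (-0.6 ± 0.044) and the actin gene ACTG2 (-0.55 ± 0.082) fell most in the average. IGHG1 fell without an endocrine agent (-0.77) and on tamoxifen (-3.91) but rose on letrozole (2.54). KLK3, DNAI7 and CCNA1 rose on tamoxifen by 2.27, 1.9 and 1.82 and differed by -0.01 to 0.2 elsewhere, with KLK3 near the floor. For the DNA replication and E2F targets, 21 of 44 fell (30 adjusted over the list alone), median -0.17, adjusted p = 1.45e-19. Of the mitotic genes, 17 of 39 fell (27 adjusted over the list alone), median -0.17, adjusted p = 3.2e-15. For the hypoxia genes, 8 of 22 rose (11 adjusted over the list alone), median 0.16, adjusted p = 9.8e-09. The mitotic average came from tamoxifen, with a median of -0.54 there and medians of 0.03 without an endocrine agent and 0 on letrozole that were not called. In the same order the medians were -0.42, -0.09 and -0.06 for the E2F targets and 0.31, 0.24 and -0.06 for hypoxia, both on letrozole called with the preset correlation alone. Another 9 lists were called with the preset correlation alone. In limma 630 genes changed, 329 higher and 301 lower. The count was 380 and 373 without control replicates 1 and 2, 388 and 374 without BMS-754807 replicates 1 and 2, and 343 without Letrozole replicate 1 or 2. It was 400 and 330 without Letrozole+BMS-754807 replicates 1 and 2, and 331 with plate column as a block.

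What tamoxifen added to BMS-754807 was read from the combination against BMS-754807. CALML5 rose by 6.48 ± 0.11 (adjusted p = 4.31e-11), CCNO by 5.8 ± 0.11, SYBU by 5.36 ± 0.17 and ABCC4 by 5.34 ± 0.084. NPY1R (-5.45 ± 0.12), ELOVL2 (-4.72 ± 0.089), DLC1 (-3.86 ± 0.15) and RAB31 (-3.67 ± 0.13) fell most among 3473 changed genes, 1579 higher and 1894 lower. Among the mitotic genes, 38 of 39 fell (38 adjusted over the list alone), median -1.26, adjusted p = 2.24e-32. Of the DNA replication and E2F targets, 38 of 44 fell (41 adjusted over the list alone), median -0.92, adjusted p = 5.13e-23. Among the oestrogen-induced genes, 31 of 42 fell and 5 rose (32 and 5 adjusted over the list alone), median -0.68, adjusted p = 3.94e-11. Of the interferon response genes, 31 of 41 rose and 2 fell (32 and 3 adjusted over the list alone), median 0.56, adjusted p = 9.77e-12. Ribosome biogenesis and androgen receptor targets were called both ways too, at medians of -0.52 and 0.39, and another 4 lists with the preset correlation alone.

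With letrozole added to BMS-754807, SERHL rose by 3.71 ± 0.082 (adjusted p = 3.14e-09), SERHL2 by 3.61 ± 0.088, IGHG1 by 3.34 ± 0.14 and PIP by 3.04 ± 0.19. PLAC1 (-2.57 ± 0.084), GREB1 (-2.41 ± 0.095), MGP (-2.4 ± 0.076) and NAV2 (-2.28 ± 0.17) fell most among 1411 changed genes, 697 higher and 714 lower. The count was 795 and 788 without BMS-754807 replicates 1 and 2, and 843 and 779 without Letrozole+BMS-754807 replicates 1 and 2. For the oestrogen-induced genes, 29 of 42 fell and 3 rose (31 and 4 adjusted over the list alone), median -0.98, adjusted p = 1.53e-24. Of the heat shock genes, 3 of 16 fell (5 adjusted over the list alone), median -0.15, adjusted p = 0.000368. Among the interferon response genes, 31 of 41 rose and 1 fell (35 and 1 adjusted over the list alone), median 0.52, adjusted p = 1.53e-24. The hypoxia (-0.24), mitotic (-0.42), E2F (-0.42), ribosome biogenesis (-0.25), oestrogen-repressed (0.38) and androgen receptor (0.07) lists were called both ways too, at the medians given, and another 4 with the preset correlation alone.

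Against letrozole, tamoxifen-treated tumours were higher in SPINK4, a protease inhibitor, by 4.78 ± 0.2 (adjusted p = 1.23e-07), KRT13 by 4.51 ± 0.11, CCNO by 3.85 ± 0.11 and RGCC by 3.64 ± 0.14. They were lower in CPB1 (-5.4 ± 0.18), CSTA (-4.23 ± 0.24), NPY1R (-3.2 ± 0.12) and AGTR1 (-2.78 ± 0.18). For the interferon response genes, 23 of 41 fell (30 adjusted over the list alone), median -0.44, adjusted p = 2.33e-16, with PSMB9 at -1.12 ± 0.1. Within plate columns 5 and 6 the interferon medians were -0.4 and -0.42. In limma 1494 genes changed, 766 higher and 728 lower, and 925 without Letrozole replicate 1 or 929 without Letrozole replicate 2. The other 9 calls were made with the preset correlation alone. For the mitotic genes, 19 of 39 fell (26 adjusted over the list alone), median -0.26, adjusted p = 8.02e-10 and adjusted p = 0.0596 with an estimated correlation. In basal epithelium 5 of 16 rose (5 adjusted over the list alone), median 0.12, adjusted p = 0.0145 and adjusted p = 0.144 with an estimated correlation, with KRT15 at 2.29 ± 0.16.

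Between the combinations, the one with tamoxifen was higher in CCNO by 5.35 ± 0.11 (adjusted p = 1.42e-09), SPINK4 by 4.99 ± 0.2, the sulfatase gene SULF1 by 4.28 ± 0.16 and ZBBX by 4.26 ± 0.15. It was lower in CPB1 (-4.62 ± 0.18), IGHG1 (-4.04 ± 0.14), NPY1R (-3.37 ± 0.12) and ADAM2 (-3.15 ± 0.22). In limma 2304 genes changed, 1051 higher and 1253 lower, and 1510 without Letrozole+BMS-754807 replicate 2. With a minimum of 1.5-fold more were higher (435) than lower (330). Of the mitotic genes, 35 of 39 fell (35 adjusted over the list alone), median -0.83, adjusted p = 7.31e-27. Among the DNA replication and E2F targets, 31 of 44 fell and 0 rose (33 and 1 adjusted over the list alone), median -0.5, adjusted p = 6.93e-15. Of the hypoxia genes, 13 of 22 rose and 1 fell (13 and 1 adjusted over the list alone), median 0.31, adjusted p = 7.83e-05. Of the androgen receptor targets, 9 of 18 rose and 1 fell (9 and 1 adjusted over the list alone), median 0.3, adjusted p = 7.51e-05. Ribosome biogenesis (median -0.19) was called both ways too, and another 4 lists with the preset correlation alone.

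Changed genes were counted in both of 2 comparisons that share the control arrays. Tamoxifen and letrozole both raised 419 genes and both lowered 479, against 71.2 and 76.4 for independent lists, and 60 moved in opposite directions. Across genes the covariance of their fold changes was 0.0571, against 0.00578 between simulated unchanged groups with the same controls. The 2 combinations shared 580 genes higher and 676 lower, against 120.1 and 138.6, with 94 opposite and a covariance of 0.0732 against 0.00569. BMS-754807 shared 26 higher and 8 lower with tamoxifen, 24 being opposite, against 5.5, 2.9 and 8.8 for independent lists, and 17 and 4 with letrozole, 25 being opposite, against 3, 1.3 and 4.2. The covariances, 0.0056 and 0.00547, lay under the simulated 0.00573 and 0.00577. Without control replicate 1 or 2 the shared counts were 511 or 476 for tamoxifen and letrozole, 715 or 723 for the combinations, and 0 or 1 and 0 or 2 for BMS-754807 with tamoxifen and with letrozole. Part of each same-direction count can come from the shared control arrays, which are too few to divide with 2 for each comparison.

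Markers of other cell types lay near the floor (list medians per group 3.07 to 3.66). Human probes may miss mouse host cells, so host content stays open. Erythroid markers lay at 3.78 to 3.91 and, with tamoxifen, at 5.29, where HBB and HBA2 were high on replicate 1 alone. Of the 41 lists, 14 were called in none of the 14 comparisons. Over the comparisons the medians ran from -0.05 to 0.12 for fibroblast markers (22 measured, lowest adjusted p = 0.105) and from -0.05 to 0.08 for endothelial markers (16, 0.362). They ran from -0.04 to 0.1 for macrophages (20, 0.114), -0.04 to 0.09 for lymphocytes (18, 0.457) and -0.07 to 0.07 for adipocytes (13, 0.289). For muscle they were -0.15 to 0.12 (17, 0.0565), for keratinocytes -0.06 to 0.08 (10, 0.383), for neural markers -0.04 to 0.13 (13, 0.0844) and for mesenchymal genes -0.06 to 0.08 (13, 0.656). For cyclin-dependent kinase inhibitors they were -0.08 to 0.13 (15, 0.381), for ribosomal proteins -0.02 to 0.03 (44, 0.264) and for TNF and NF-kB targets -0.02 to 0.07 (24, 0.164). The BCL2 family ran from -0.11 to 0.1 (16, 0.233) and aryl hydrocarbon receptor targets from -0.13 to -0.01 (9, 0.207). In 75 of 574 list tests, 0 called, the median or mean differed in sign from the test (medians up to 0.21).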

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

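The contrast of the BMS-754807 effect on tamoxifen with that on letrozole, the list of multiciliated cell genes, the list of immunoglobulin genes and the test of tumour cell share were chosen only after results were seen.

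The effect of BMS-754807 differed between backgrounds by the interaction test. With tamoxifen it differed from BMS-754807 alone in 386 genes (193 to 390 without 1 of the 8 arrays). Medians of the list interactions were -0.4 for oestrogen-induced genes, 0.34 for androgen receptor targets, -0.15 for MAPK genes, -0.55 for mitotic genes and -0.35 for E2F targets. They were -0.18 for fatty acid synthesis, -0.14 for glycolysis, -0.14 for ribosome biogenesis, 0.34 for the interferon response and 0.07 for milk genes. With an estimated correlation 6 of these 10 calls were kept, and those of MAPK genes (adjusted p = 0.207), fatty acid synthesis (0.402), glycolysis (0.244) and milk genes (0.158) were lost. MAPK genes and fatty acid synthesis also lost the call without any 1 of 3 arrays, and glycolysis without 1. The gene interactions were 2.16 for S100A8, 2.13 for KLK3, 1.95 for ZBBX, 1.92 for ZMYND10, -3.14 for IGHG1, -2.12 for RASGRP1, -1.73 for SCUBE2 and -1.34 for ELOVL2, of which ZMYND10 lost its call without any 1 of 5 arrays.

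With letrozole the effect differed from that of BMS-754807 alone in 19 genes (2 to 9 without 1 of the 8 arrays). The list medians were -0.28 for oestrogen-induced genes, 0.06 for oestrogen-repressed genes, -0.14 for androgen receptor targets, -0.1 for FOXO targets and -0.11 for cholesterol biosynthesis. They were -0.19 for glycolysis, -0.4 for hypoxia, -0.15 for endoplasmic reticulum stress, -0.13 for heat shock and -0.22 for class I genes. With an estimated correlation 3 of these 10 calls were kept. Those of oestrogen-repressed genes (adjusted p = 0.127), androgen receptor targets (0.128), FOXO targets (0.0776), cholesterol biosynthesis (0.188), glycolysis (0.0561), heat shock (0.0776) and class I genes (0.128) were lost. The first 2 and cholesterol biosynthesis also lost the call without any 1 of 4 arrays. The gene interactions were 3.3 for IGHG1, 1.17 for IGFBP5, 1.04 for CYP26A1, 1.01 for KYNU, -1.26 for SGK3, -1.23 for DDIT4, -1.1 for GREB1 and -1.01 for PLAC1. IGHG1 and DDIT4 kept the call without any 1 array, and the other 6 lost it in 7 or 8 of the 8 cases. The effect on tamoxifen differed from that on letrozole in 643 genes (297 to 506 without 1 of the 8 arrays, 401 in a fit to the compared groups alone), with medians of -0.51 for mitotic genes, 0.42 for hypoxia genes and 0.39 for interferon response genes. Outside the gene tests, 39 probe sets naming no single gene were at least 2-fold above control in some treated group.

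Mitotic genes were lower in Tamoxifen+BMS-754807 than in Tamoxifen. Without any 1 of the 4 arrays the list median lay between -0.6 and -0.52, which argues against a single array. It was -0.62 in plate column 5 and -0.5 in 6, which both groups shared, but their rows differed. A smaller tumour cell share would lower luminal genes too. Their median of 0.08 (lower quartile -0.05) argues against it, but treatment can move them. Proliferation itself was not measured.

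IGHG1 was high in Tamoxifen and in Letrozole+BMS-754807 and lower in the other groups, and its source stays open. Immunoglobulin-producing cells of the host would raise other such genes, whose median difference was -0.01, under the bound of 0.2 set beforehand. That bound was unusable, because 13 of the 18 genes lay under 3.44, the level of the dimmest genes, and 3 of the other 5 within 0.2 of it (IGHM, CD27 and PRDM1, with differences of 0.01, -0.1 and 0); this reading was chosen after the value was seen. The plasma cell gene MZB1, at 4.19 to 5, differed by -0.01, which counts against host cells but is 1 gene. SDC1, at 0.68, is a gene of epithelium too. Of 54 other immunoglobulin probe sets, 0 followed IGHG1 over the group means with a correlation over 0.9 (highest 0.856), but 45 of them lay under 3.44, so an aberrant probe set cannot be told apart from host cells either, a reading also chosen after the value was seen. No effect of the treatments on IGHG1 in tumour cells was tested.

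Some genes of motile cilia were higher in Tamoxifen+BMS-754807 than in Tamoxifen. A shift of all dim genes is argued against by the median of 0.018 over the 3650 dimmest genes. Multiciliated cell genes other than those already named were higher as a list (14 of 36 past limma, 22 not, median 0.2, camera p = 1.39e-11 in limma, p = 0.000225 with an estimated correlation), so the rise was not limited to the named genes. Why these genes rose was not tested.

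The average BMS-754807 effect changed 630 genes. Of 100 regroupings of the arrays within each background, drawn from 108, 1 gave as many genes, the real one. The next (502) kept the tamoxifen groups and exchanged whole groups in the other 2 backgrounds. Splitting a group puts treatment differences into the residual, so chance is not excluded. Nor does the count show an effect common to the 3 backgrounds.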

How the results depend on the processing

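The contrast of BMS-754807 on tamoxifen with that on letrozole was tested only after the data were seen. No named gene or list call turned its direction in any alternative. Of 655 gene calls and non-calls, 646 kept their side of the threshold with array weights and 636 with the replicate block. A further quantile normalisation kept 651, plate column as a block 624, a trended robust prior 607 and probe set means 604. Testing every probe set kept 644, each read from the gene's same probe set. Leaving out the dimmest 30% of genes kept 628 of 650 and a fit to the compared groups alone 543 of 612, losing 69. Leaving out 1 array kept 2790 of 3248 such results and 739 of 800 list calls. Of 156 list calls 16 ended without the dimmest 30% of genes, 6 with a further quantile normalisation and 2 with the plate block. The replicate block ended 1 and array weights 0. All also ended with an estimated correlation. A lone array left in a group is assumed to vary like the other groups. Dim genes lie near background, where a difference reads smaller. The cause of the changes below was not tested, apart from fewer genes or arrays or a stricter threshold.

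With the dimmest 30% of genes left out, changed genes numbered 120 for BMS-754807 against control (78 with all genes), 172 for what BMS-754807 added to letrozole (91) and 35 for the letrozole interaction (19), and 39 were shared by BMS-754807 and letrozole (21). A trended robust prior gave 375 for BMS-754807 against control, 1595 for what it added to tamoxifen (1063) and 438 for what it added to letrozole. It gave 805 for the tamoxifen interaction (386), 134 for the letrozole interaction, 1194 for the average (630) and 1134 for the contrast of the 2 backgrounds (643). Plate column as a block gave 34, 30, 11 and 331 for BMS-754807 against control, its addition to letrozole, the letrozole interaction and the average. With every probe set tested on its own, the addition to letrozole changed 139 probe sets, which are not a count of genes, and array weights gave 30 for the letrozole interaction.

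With a minimum of 1.5-fold the counts against control were 30 for BMS-754807, 827 for Tamoxifen (2692), 329 for Letrozole (1336), 1348 for Tamoxifen+BMS-754807 (3635) and 404 for Letrozole+BMS-754807 (1733). They were 279 and 26 for BMS-754807 added to tamoxifen and to letrozole, 1284 (3473) and 376 (1411) for these agents added to BMS-754807, 525 (1494) between the agents and 765 (2304) between the combinations. The average had 13 and the contrast of backgrounds 383. This minimum turned a majority of lower genes into one of higher genes for Tamoxifen (468 to 359) and Tamoxifen+BMS-754807 (689 to 659) against control, for BMS-754807 added to tamoxifen (172 to 107), letrozole added to BMS-754807 (232 to 144), between the combinations (435 to 330), for the tamoxifen interaction (140 to 126) and for the contrast of backgrounds (213 to 170). Shared genes numbered 6 (34) for BMS-754807 and tamoxifen, 3 for BMS-754807 and letrozole, 212 (898) for tamoxifen and letrozole and 286 (1256) for the combinations. A limma fit to the compared groups alone gave 0 for BMS-754807 against control (1581 at an unadjusted p under 0.05), 271 and 6 for its addition to tamoxifen and to letrozole, 891 between the endocrine agents, 253 for the tamoxifen interaction and 401 for the contrast of backgrounds.

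The replicate numbers do not pair the samples, since the 15 correlations of residuals between groups ran from -0.06 to 0.12 with a median of 0.01. As a block they gave 38 genes for BMS-754807 added to letrozole and 9 for the letrozole interaction. List calls numbered 156 with the preset correlation, 76 with an estimated one and 288 with fry, which tests whether a list's genes move and does not compare them with other genes.

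Leaving out each array in turn gave 0 to 5 genes for BMS-754807 against control (limma, 1205 at an unadjusted p under 0.05 where it was 0), 661 to 735 for Letrozole and 948 to 1042 for Letrozole+BMS-754807. It gave 550 to 885 for BMS-754807 added to tamoxifen, 6 to 16 for its addition to letrozole, 779 to 843 for letrozole added to BMS-754807, 925 to 1168 between the endocrine agents and 1510 to 1682 between the combinations. The tamoxifen interaction ran from 193 to 390, the letrozole interaction from 2 to 9, the average from 330 to 633 and the contrast of backgrounds from 297 to 506. Shared genes ran from 0 to 1, 0 to 2, 476 to 511 and 715 to 723 in the order given above.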

Other observations

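The list of multiciliated cell genes was chosen only after ZBBX, DNAI7 and ZMYND10 had been seen, and its tests were not planned. Of 36 measured genes of the list, 16 rose and 0 fell in Tamoxifen+BMS-754807 against control (median 0.21, camera p = 8.59e-08, or p = 0.000796 with an estimated correlation). In Tamoxifen 10 rose (median 0.05, p = 0.00369, or p = 0.015 with an estimated correlation), and in BMS-754807, Letrozole and Letrozole+BMS-754807 1 rose in each, with p = 0.769, 0.685 and 0.567 by camera in limma, and 2 fell in the last. The tamoxifen interaction was positive in 10 genes and negative in 0 (median 0.24), but some genes lay near the floor without tamoxifen. Against Tamoxifen, FOXJ1, a transcription factor of motile cilia, rose by 1.68 ± 0.16 in Tamoxifen+BMS-754807. There TPPP3 rose by 1.71 ± 0.16, DNAAF11 by 1.61 ± 0.15 and DNALI1 by 1.34 ± 0.1. FOXJ1 lay at 3.57 in control, 5.75 in Tamoxifen, 7.42 in Tamoxifen+BMS-754807 and 3.37 to 3.43 in the others.

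Of 2491 probe sets naming no single gene, limma found 3, 265, 128, 374 and 185 changed against control in BMS-754807, Tamoxifen, Letrozole, Tamoxifen+BMS-754807 and Letrozole+BMS-754807. The largest rise was 3.46, in Letrozole, and the largest fall was -3.18, in Tamoxifen+BMS-754807.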
